A study of Homo sapiens with 4 samples.

How the data were processed

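Messenger RNA was measured in 2 human bladder cancer cell lines, T24 and 5637, each cultured with or without the steroidal saponin protodioscin for 6 h. There were 4 libraries, 1 for each line and treatment, so no group had a replicate. The sample titles give the dose as 60 µM for T24 and 70 µM for 5637, whereas the treatment protocol gives the same numbers in millimolar, and the unit of the titles was used here. The labels call the controls untreated and name no vehicle. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit, libraries were made with the Illumina TruSeq RNA v2 kit, which selects polyadenylated RNA and does not mark strand, and paired-end reads of 150 bases were sequenced on a HiSeq2500.

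The authors deposited gene-level FPKM (fragments per kilobase of transcript, scaled to library size) for all 4 libraries. Trimmomatic, HISAT2, StringTie and the genome build GRCh38 are named in the submitters' processing notes, and their versions, their settings and the gene annotation release are not given in the sources used here. FPKM corrects for library size and transcript length, but not for a few abundant transcripts taking a larger part of a library. StringTie also divides reads between overlapping transcripts by an estimate, so the values of genes that share exons depend on each other. The table held 60617 Ensembl gene IDs, of which 27829 were above 0 in at least 1 library. Symbols were found for 42110 IDs in a table of gene names and in GENCODE 29, and 58542 IDs were in GENCODE 29, which gave gene types, coordinates on GRCh38, transcript length, GC content and exon overlap between genes (bedtools 2.31.1).

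The sums of FPKM were 325580 in untreated T24, 322821 in treated T24, 338385 in untreated 5637 and 348577 in treated 5637. Read totals were not part of the table. The spacing of the lowest values, which is what 1 read is worth, gave the relative depth: 1.28 times that of untreated T24 for treated T24, 1.43 times for untreated 5637 and 1.20 times for treated 5637. On a transcript of 1 kb, 1 read was worth 0.0171 to 0.0246 FPKM, so counting error was small for genes at 1 FPKM or more on longer transcripts and larger for short RNAs. Whole read counts could not be recovered for nearly all genes, so no count test was run.

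Values were analysed as log2(FPKM + 1) with pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15, and fold changes on this scale understate the change of genes with low values. Within a line, a gene was compared where it reached 1 FPKM in at least 1 of the 2 libraries, and a difference of 1 on the log2 scale (2-fold) was the size rule. With 1 library per group, differences within a line have no replicate check and no p-value was computed for them. The effect of treatment over both lines and the difference between the lines were tested with limma 3.58.1 in R 4.3.3, in a fit over all 4 libraries with cell line and treatment as terms and a trended prior variance. It covered genes at 1 FPKM or more in at least 2 of the 4 libraries. The fit had 1 residual degree of freedom, which holds the difference between the responses of the lines at their different doses. Calls were made at a Benjamini-Hochberg adjusted p below 0.05. The labels do not say whether the cultures were independent, so these p-values measure only the spread between these libraries.

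The fit was tested on simulated data in 20 draws of 12893 genes, with noise drawn from the fitted prior variance. In each draw, 50 genes were changed by treatment at each size. The fit recovered 43.8% of genes changed by 0.5 on the log2 scale, 97% of those changed by 1 and 100% of those changed by 2 or 4. The larger changes ease the adjusted threshold for the smaller ones, so these shares do not give the power where few genes change. The median number of false calls per draw was 12 and the highest was 41, with 8.4% of all calls false.

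Fixed gene lists, 33 in number with 442 genes, covered sterol and lipid metabolism, stress responses, signalling, apoptosis, the cell cycle, cell identity, RNA quality and markers of other cell types, and 441 of their genes were found. For each list and line, the median change was placed among 10000 random lists of the same size matched on mean expression in 10 classes. The percentile describes these libraries and is not a p-value, since members of a list are regulated together and their median can differ between any pair of libraries. Of 100 random lists of 15 genes in T24, 5% lay outside the central 95% of their own random lists. For the treatment effect and the line effect, the number of members called was also computed with p-values adjusted over the list alone, with no correction for the number of lists.

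The text names the 8 genes with a symbol that had the largest difference in each direction in each line, the 10 in each direction with the largest smaller-of-both difference in the same direction in both lines, the 8 in each direction with the largest coefficient between the lines, members of the lists, and list members at 2-fold. This rule, the model, the lists and the alternatives except the one without exon-sharing genes were fixed before the data were examined, whereas the closing tests of scaling, of line or dose and of shared handling were chosen afterwards. Because most of the largest changes fell on genes that share exons with another gene on the same strand, the same rule was applied afterwards to genes without such overlap, taking 10 genes per line and direction and 12 over both lines. Genes named by this second rule were therefore chosen after their values were seen. A few genes that these rules select are not reported here. The alternatives were a pseudocount of 0.1 or 5, no filter or a filter at 5 FPKM, median-ratio, TPM and quantile scaling, protein-coding genes alone, a size rule of 1.5-fold, limma without the block for cell line (or for treatment, between the lines) and limma without the trend. The restriction to genes without same-strand exon overlap was added after the data were seen. Leaving out a library was not possible, because no residual degree of freedom would have been left. Confidence intervals of shares are exact (Clopper-Pearson) at 95% and cover counting error only.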

Results

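The series asked how the mRNA profile of different bladder cancer lines responds to protodioscin, a steroidal saponin found in plants such as yam and fenugreek. T24 and 5637 are established lines from human urinary bladder carcinomas. Each line gave 1 untreated library and 1 library after 6 h of protodioscin, at 60 µM in T24 and at 70 µM in 5637. Between 11941 and 12405 genes reached 1 FPKM in a library. The 100 most abundant genes held 24.2% and 23.5% of the FPKM sum in untreated and treated T24, and 27.2% and 28.6% in untreated and treated 5637. Transcripts of the mitochondrial genome held 4.50% and 3.74% of the sum in T24, and 9.84% and 11.9% in 5637. There was no replicate within a group, so the values below carry no error within a line.

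In T24 treated with protodioscin, transcripts of RGS4, EDN1, S1PR1 and IGFBP5 were at lower levels than in untreated cells, and those of the cell cycle inhibitor CDKN1A were at higher levels. RGS4, a regulator of G-protein signalling (ENSG00000117152, chromosome 1, 163068775 to 163076802 on GRCh38), was at 27.9 FPKM in untreated and 10.6 FPKM in treated cells, a log2 difference of -1.32. EDN1, which encodes the vasoactive peptide endothelin-1, was at 6.35 and 2.02 FPKM (-1.28). S1PR1, a receptor for sphingosine-1-phosphate, was at 2.99 and 0.927 FPKM (-1.05), and IGFBP5, a binding protein of insulin-like growth factors, was at 9.46 and 4.18 FPKM (-1.02). CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339) was at 30.4 FPKM untreated and 54.2 FPKM treated, a log2 difference of 0.82.

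Among genes that share no exon with another gene on the same strand, DHRS2, a short-chain dehydrogenase/reductase, was at 6.76 and 14.4 FPKM (0.99) in T24. The membrane protein gene ITM2B was at 21.4 and 40.7 FPKM (0.89), the palmitoyltransferase gene ZDHHC3 at 5.86 and 12.2 FPKM (0.94) and the nuclear receptor coactivator PNRC1 at 3.24 and 7.09 FPKM (0.93). The mitochondrial ribosomal protein gene MRPS23 was at 14.2 and 4.26 FPKM (-1.53). RPS23, a protein of the small cytosolic ribosomal subunit, was at 145 and 68.8 FPKM (-1.06) and was the only member of the fixed lists at 2-fold in either line. S1PR1, IGFBP5, ITM2B, ZDHHC3 and PNRC1 were chosen after their values were seen. The microRNA gene MIR324 was listed at 0 and at 3.54 FPKM and the small nucleolar RNA gene SNORA23 at 0 and at 1.61 FPKM, and both are short genes whose reads are few in libraries of polyadenylated RNA.

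Early targets of YAP and TGF-beta signalling were lower in treated T24. The median of the list was -0.37 on the log2 scale, 6 of its 8 measured members were below 0, and all 10000 random lists lay above it; the median was -0.21 without exon-sharing genes. ANKRD1, a YAP target, was at 38.9 FPKM untreated and 19.97 FPKM treated (-0.93), and the matricellular genes CCN1 and CCN2 were at 209 and 132 FPKM (-0.66) and at 61.1 and 40.9 FPKM (-0.57). Interferon-stimulated genes were higher, with all 12 members above 0 and a median of 0.26. Among them, IFIT1 was at 43.8 and 60.1 FPKM and OAS1 at 39.3 and 50.9 FPKM. The p53 targets had a median of 0.23 (0.13 with a pseudocount of 5), with 11 of 14 members above 0, among them RRM2B, a ribonucleotide reductase subunit, at 5.04 and 6.96 FPKM (0.40). Immediate early and AP-1 genes had a median of 0.28, with 11 of 16 members above 0. In that list EGR1 and FOS, both induced early by mitogens, were at 7.15 and 12.002 FPKM and at 1.57 and 2.89 FPKM, whereas MYC was at 42.8 and 25.5 FPKM (-0.73).

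The median in T24 was 0.16 for ATF4 and CHOP targets (14 of 18 members above 0), 0.15 for NRF2 antioxidant genes (12 of 13), 0.16 for lysosome and autophagy genes (11 of 14) and 0.087 for endoplasmic reticulum chaperones (17 of 19). CHAC1, an ATF4 target that degrades glutathione, was at 3.67 and 5.47 FPKM (0.47), and the autophagy gene WIPI1 was at 6.07 and 9.19 FPKM (0.53). Cholesterol synthesis and uptake genes had a median of -0.087 with 17 of 24 members below 0, and mesenchymal and migration genes a median of -0.093 with 11 of 15 below 0. The chaperones were within the range of random lists without a filter and without exon-sharing genes, and the mesenchymal genes with TPM or quantile scaling. Along with these lists, mitochondrially encoded transcripts had a median of -0.27 (10 of 11 members below 0, and -0.15 with quantile scaling) and non-polyadenylated and nuclear RNAs a median of -0.31 (6 of 9 below 0, with -0.013, within the range, without a filter and 0.33 for the 3 protein-coding members alone) in the treated T24 library, which was also sequenced 1.28 times as deeply as the untreated library.

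In T24, 25 genes were at least 2-fold higher and 34 at least 2-fold lower among the 12193 compared, and 96.7% of genes differed by less than 0.5 on the log2 scale. Most of the largest differences lay on genes whose exons belong to more than 1 gene. Of the 59 genes at 2-fold, 44 (74.6%) shared exons with another gene on the same strand, against 18.3% of all genes compared. They included the read-through loci BLOC1S5-TXNDC5 (9.06 and 0.162 FPKM), SENP3-EIF4A1 (37.6 and 3.82 FPKM), HSPE1-MOB4 (9.67 and 2.84 FPKM) and, in the other direction, ATP6V1G2-DDX39B (2.90 and 28.2 FPKM), ARL2-SNX15 (0.216 and 6.01 FPKM), RPL36A-HNRNPH2 (1.90 and 6.99 FPKM), CORO7-PAM16 (1.45 and 5.58 FPKM) and ARPIN-AP3S2 (0.712 and 3.30 FPKM). TOMM6, TNFRSF6B and the protocadherin PCDHGB4 also shared exons with a neighbour. Values of such genes are uncertain, because DDX39B itself, for example, was at 107 and 59.2 FPKM while ATP6V1G2-DDX39B was higher. Without genes that share exons on the same strand, 3 were at least 2-fold higher and 12 at least 2-fold lower. Among the lower ones, TUBA1B-AS1, RPS23 and IGFBP5 share exons with a gene on the opposite strand, which libraries without strand do not separate. The gene opposite IGFBP5 was listed at 0 in both T24 libraries, and ATG10, opposite RPS23, was at 2.56 and 3.22 FPKM there.

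In 5637 treated with protodioscin, transcripts of AQP3, KRT10 and HAS2 were at lower levels than in untreated cells, as were most genes of the basal and squamous urothelial list, and those of ME2 and GSTM3 were at higher levels. AQP3, a water and glycerol channel (ENSG00000165272, chromosome 9, 33441154 to 33447633), was at 32.02 FPKM untreated and 13.7 FPKM treated, a log2 difference of -1.17. KRT10, a keratin of differentiating squamous epithelium, was at 24.7 and 10.9 FPKM (-1.11) in 5637 and at 8.69 and 14.6 FPKM (0.69) in T24, and HAS2, a hyaluronan synthase, was at 17.2 and 8.86 FPKM (-0.89) in 5637. ME2, the mitochondrial malic enzyme (ENSG00000082212, chromosome 18, 50878734 to 50954257), was at 4.66 and 10.7 FPKM (1.05), and GSTM3, a glutathione transferase, was at 1.43 and 3.71 FPKM (0.96). DHRS2 was at 1.10 and 2.66 FPKM (0.80), the Wnt pathway gene PYGO1 at 1.96 and 4.18 FPKM (0.81), the glutaredoxin gene GLRX2 at 3.18 and 6.28 FPKM (0.80) and the zinc finger gene ZNF528 at 0.686 and 1.89 FPKM (0.78). In T24, GLRX2 and PYGO1 were lower with treatment, at 7.80 and 5.165 FPKM (-0.51) and at 3.46 and 2.67 FPKM (-0.28). ME2, GSTM3 and ZNF528 were higher in T24 as well (0.45, 0.33 and 0.14), and HAS2 was lower (-0.33). AQP3 was at 0.807 and 0.881 FPKM there. GLRX2 shares exons with RO60 on the opposite strand, whose reads libraries without strand do not separate. RO60 was at 7.81 and 8.25 FPKM in T24 and at 7.07 and 8.25 FPKM in 5637. LINC01128 and SMARCA5-AS1 were at 2.80 and 1.66 FPKM in untreated and were listed at 0 in treated cells. The reads of antisense genes such as SMARCA5-AS1 cannot be separated from those of the gene opposite in libraries without strand.

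Basal and squamous urothelial genes had a median of -0.29 in 5637, with 11 of 12 members below 0, and all 10000 random lists lay above it. TP63, the transcription factor of basal epithelium, was at 27.9 FPKM untreated and 19.2 FPKM treated (-0.51). The basal keratin KRT6A was at 574 and 432 FPKM (-0.41), KRT5 at 331 and 283 FPKM (-0.22), and KRT16 at 4.39 and 2.61 FPKM (-0.58). AQP3, KRT10, HAS2, GSTM3, PYGO1, GLRX2 and ZNF528 were chosen after their values were seen. Luminal genes had a median of -0.18 with 7 of 9 members below 0 (-0.015, within the range of random lists, without a filter), among them PPARG, a nuclear receptor of urothelial differentiation, at 50.4 and 37.5 FPKM (-0.42). GATA3, of the same list, was at 14.5 and 17.0 FPKM (0.22). Epithelial genes had a median of -0.098 (9 of 12 below 0, and -0.16 with median-ratio scaling) and mesenchymal and migration genes a median of -0.17 (12 of 14 below 0, and -0.093 without a filter), with the collagenase gene MMP1 at 1912 and 1530 FPKM, the related MMP10 at 32.1 and 22.5 FPKM and fibronectin (FN1) at 235 and 191 FPKM.

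MAPK feedback genes had a median of -0.12 in 5637 (11 of 15 members below 0), fatty acid synthesis genes -0.11 (8 of 9 below 0) and immediate early and AP-1 genes -0.094 (9 of 16 below 0). The last was at 0.015, on the other side of 0, without a filter on low values. DUSP4, a phosphatase that limits ERK signalling, was at 116 and 93.3 FPKM, and FASN, the fatty acid synthase, was at 55.3 and 47.3 FPKM. Lysosome and autophagy genes had a median of 0.18 (11 of 13 above 0), NRF2 genes 0.13 (9 of 12), ATF4 and CHOP targets 0.11 (13 of 18) and cholesterol genes 0.11 (20 of 23). With median-ratio scaling the medians were 0.074 for NRF2 genes, 0.052 for ATF4 and CHOP targets, 0.056 for cholesterol genes, -0.17 for fatty acid synthesis genes, -0.18 for MAPK feedback genes and -0.15 for immediate early genes, each still outside the central 95% of random lists. ATF4 and CHOP targets and cholesterol genes were within that range with a filter at 5 FPKM, NRF2 genes with TPM scaling or a pseudocount of 0.1, and NRF2, cholesterol and fatty acid synthesis genes without exon-sharing genes. ASNS, the asparagine synthetase, was at 5.11 and 8.76 FPKM (0.68), and STARD4, a sterol carrier, was at 1.79 and 2.90 FPKM (0.49). Along with these lists, mitochondrially encoded transcripts had a median of 0.32 (11 of 11 above 0, and 0.14 with quantile scaling) and non-polyadenylated and nuclear RNAs a median of 0.32 (6 of 8 above 0, with 0.12 with TPM scaling and 0.094 for protein-coding members alone, both within the range) in the treated 5637 library, whose relative depth was 1.20 against 1.43 for the untreated library.

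In 5637, 22 genes were at least 2-fold higher and 27 at least 2-fold lower among 12635 compared, and 97.9% of genes differed by less than 0.5 on the log2 scale. Of the 47 changed genes with an annotation, 33 (70.2%) shared exons on the same strand, against 17.8% of genes compared. IFI30, a lysosomal thiol reductase, and PIK3R2, a regulatory subunit of PI3-kinase, were at 9.39 and 1.72 FPKM and at 21.1 and 7.12 FPKM, while the annotated gene that joins them (ENSG00000268173) was at 0.222 and 13.1 FPKM. TOMM6, NDUFC2-KCTD14, SENP3-EIF4A1, the MATR3 gene annotated as ENSG00000280987, SKP1P1, SCHIP1, ATXN7 and SNORD125 had the largest differences upward among genes with a symbol, and INO80B-WBP1, BLOC1S5-TXNDC5 and MIR3142HG were among the largest downward. All of these share exons. Without genes that share exons on the same strand, 6 were at least 2-fold higher and 8 at least 2-fold lower. Some of the lower ones, such as TUBA1B-AS1 and KRT10, share exons with a gene on the opposite strand. The gene opposite KRT10, KRT10-AS1, was at 1.84 and 1.605 FPKM in untreated and treated 5637.

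**Figure D1:**
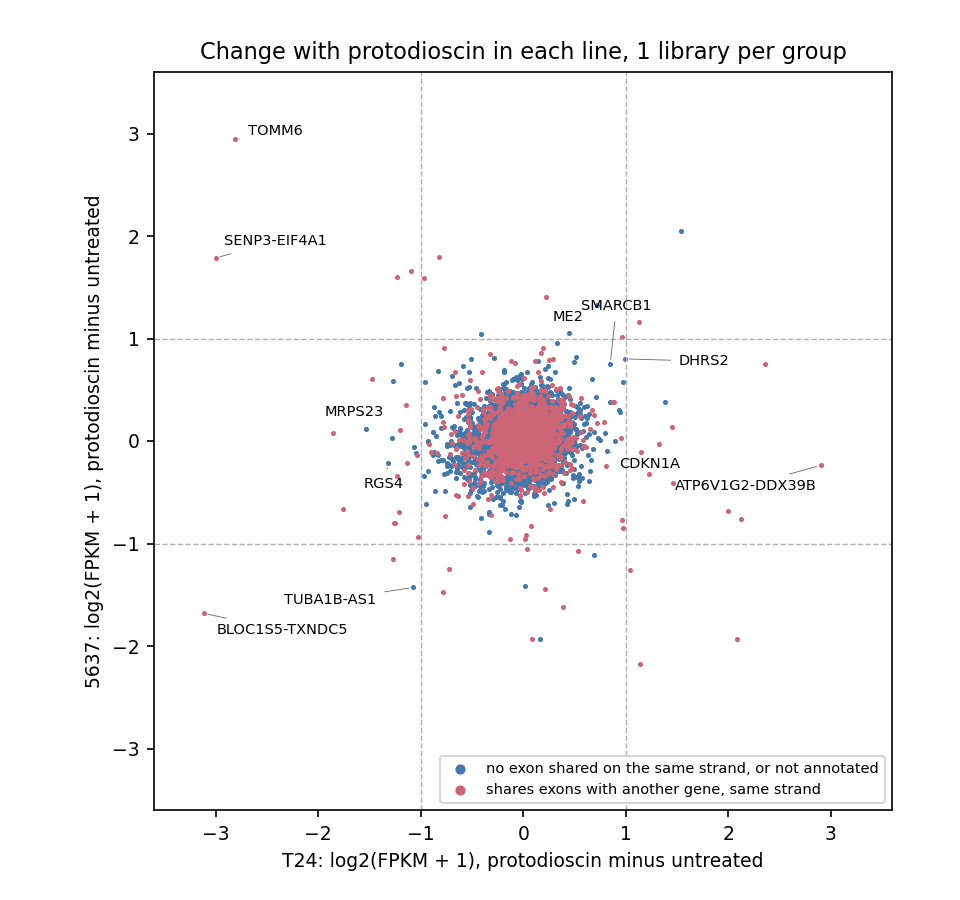
Each point is a gene at 1 FPKM or more in at least 1 library of each line (11417 genes), with the difference of log2(FPKM + 1) between treated and untreated cells for T24 on the x axis and for 5637 on the y axis; dashed lines mark 2-fold. Most genes lie near 0, DHRS2 lies at 0.99 and 0.80, and many far points are genes that share exons on the same strand (red).

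In both lines, treated cells had higher transcript levels of the stress and growth factor response genes ATF3 and EGR1, of the chromatin remodelling subunit SMARCB1 and of DHRS2, and lower levels of LYPD1, CNN2 and NCKAP1. SMARCB1 (ENSG00000099956, chromosome 22, 23786931 to 23838008) was at 29.2 and 53.3 FPKM in T24 and at 40.9 and 69.3 FPKM in 5637. EGR1, a zinc finger transcription factor, was at 7.15 and 12.002 FPKM in T24 and at 3.58 and 5.99 FPKM in 5637. ATF3, a transcription factor of the integrated stress response, was at 6.81 and 10.0 FPKM in T24 and at 1.81 and 3.80 FPKM in 5637. GABARAPL1, an autophagy protein of the ATG8 family, was at 5.02 and 7.13 FPKM in T24 and at 4.08 and 5.96 FPKM in 5637. The histone gene H2BC4 (2.495 and 4.01 FPKM, then 3.30 and 6.60 FPKM), the polarity gene PALS2 (3.33 and 4.89 FPKM, then 5.01 and 7.61 FPKM) and EPHX1, the microsomal epoxide hydrolase (18.3 and 24.3 FPKM, then 7.69 and 10.9 FPKM), were also higher in both. So was ME2, at 14.6 and 20.3 FPKM in T24 and at 4.66 and 10.7 FPKM in 5637. EPHX1 here, and LYPD3, CNN2, NCKAP1, RAPGEF3 and P2RY2 among the lower genes, were chosen after their values were seen. EPHX1 shares exons with TMEM63A on the opposite strand, which libraries without strand do not separate. TMEM63A was at 6.76 and 7.42 FPKM in T24 and at 15.8 and 14.0 FPKM in 5637.

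Lower in both lines were LYPD1, a GPI-anchored surface protein, at 106 and 73.4 FPKM in T24 and at 29.2 and 18.3 FPKM in 5637, and its relative LYPD3, at 5.97 and 4.11 FPKM and at 36.9 and 25.1 FPKM. CNN2, an actin-binding calponin, was at 158 and 117 FPKM in T24 and at 216 and 154 FPKM in 5637. NCKAP1, a subunit of the WAVE complex that drives actin branching, was at 14.6 and 10.2 FPKM and at 12.7 and 9.14 FPKM. RAPGEF3, a cyclic AMP-activated exchange factor of RAP1, was at 6.20 and 3.24 FPKM and at 4.42 and 2.87 FPKM, and P2RY2, a nucleotide receptor, was at 2.13 and 1.30 FPKM and at 10.996 and 7.24 FPKM. TUBA1B-AS1 was at 5.31 and 1.998 FPKM and at 3.01 and 0.490 FPKM, beside an opposite gene, TUBA1B, at 1734 and 1752 FPKM in T24 and at 1366 and 1399 FPKM in 5637, whose reads cannot be separated from those of TUBA1B-AS1 without strand. DLGAP1-AS1 and MIR4690 were lower in both lines as well, at log2 differences of -0.52 and -0.95 in T24. PMF1-BGLAP, PCDHGB7, ABHD14A-ACY1, TNFRSF6B and BLOC1S5-TXNDC5, lower in both, and RAB4B-EGLN2 and TM7SF2, higher in both, share exons with a neighbour.

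Across both lines, limma called 0 of 12893 genes at an adjusted p below 0.05. At an unadjusted p below 0.05 there were 1227 genes, 719 of them higher and 508 lower, where 645 would be expected by chance. The median difference over all genes compared was above 0, at 0.025 in T24 and 0.043 in 5637. With median-ratio scaling it was 0.0059 and -0.013. The split into higher and lower genes, and the counts of list members above 0, were not corrected for this shift. The lowest adjusted p from limma was 0.0784, shared by SMARCB1 (log2 difference 0.80, SE 0.064) and 3 genes without a symbol. Among genes without same-strand exon overlap, SMARCB1 reached a limma adjusted p of 0.0198, and over all alternatives that kept the block for cell line its adjusted p ranged from 0.0198 to 0.742, and it was 0.999993 without the block. With p-values adjusted over the list alone, limma called 16 genes in 8 lists, 10 higher and 6 lower. In the immediate early list these were EGR1, ATF3, FOS, JUN and JUND, which were higher, and MYC, FOSL1 and IER2, which were lower. Other genes called in this way included the heat shock genes HSPA1A and HSPA1B (both 0.34, and nearly identical in sequence), the small heat shock gene HSPB1 (-0.31), the metallothionein MT2A (0.31), GABARAPL1 (0.44), DUSP4 (-0.42) and the keratin KRT19 (-0.48). ATF3 was also called in the ATF4 and CHOP list. These calls were not corrected for the number of lists, and no list member passed over all genes.

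The lists that lay outside the central 95% of random lists in the same direction in both lines were ATF4 and CHOP targets, NRF2 genes and lysosome and autophagy genes (higher), and mesenchymal and migration genes (lower). Of these, lysosome and autophagy genes stayed outside in both lines under every alternative, while ATF4 and CHOP targets and NRF2 genes in 5637 and mesenchymal genes in T24 were inside the range under at least 1 alternative. In the NRF2 list, NQO1, a quinone reductase, was at 71.9 and 82.3 FPKM in T24 and at 26.6 and 29.3 FPKM in 5637, and SRXN1, a sulfiredoxin, was at 33.8 and 37.6 FPKM and at 18.2 and 22.9 FPKM. The receptor gene SQSTM1, of the autophagy list, was at 80.5 and 99.9 FPKM and at 59.7 and 66.1 FPKM. Of 58 list medians, 25 lay outside this range, where 2.9 would be expected for unrelated genes. At 2-fold, 3 genes were higher in both lines and 3 were lower in both, against 0.0196 and 0.0387 for independent lists, and 7 went in opposite directions. No expected number was computed for opposite directions, so these counts alone do not show that the lines responded alike. Without genes that share exons on the same strand, 1 was higher and 1 lower in both lines, and 0 went in opposite directions. The higher gene, ENSG00000267904, was listed at 0 in both untreated libraries. The lower gene was TUBA1B-AS1, whose reads cannot be separated from those of TUBA1B without strand. Across the 11417 genes compared in both lines, the differences had a Pearson correlation of 0.123 (0.190 without exon-sharing genes and 0.0960 without a filter) and a Spearman correlation of 0.189; genes are not independent replicates. The responses of the lines were not tested against each other, and their doses differed.

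**Figure D2:**
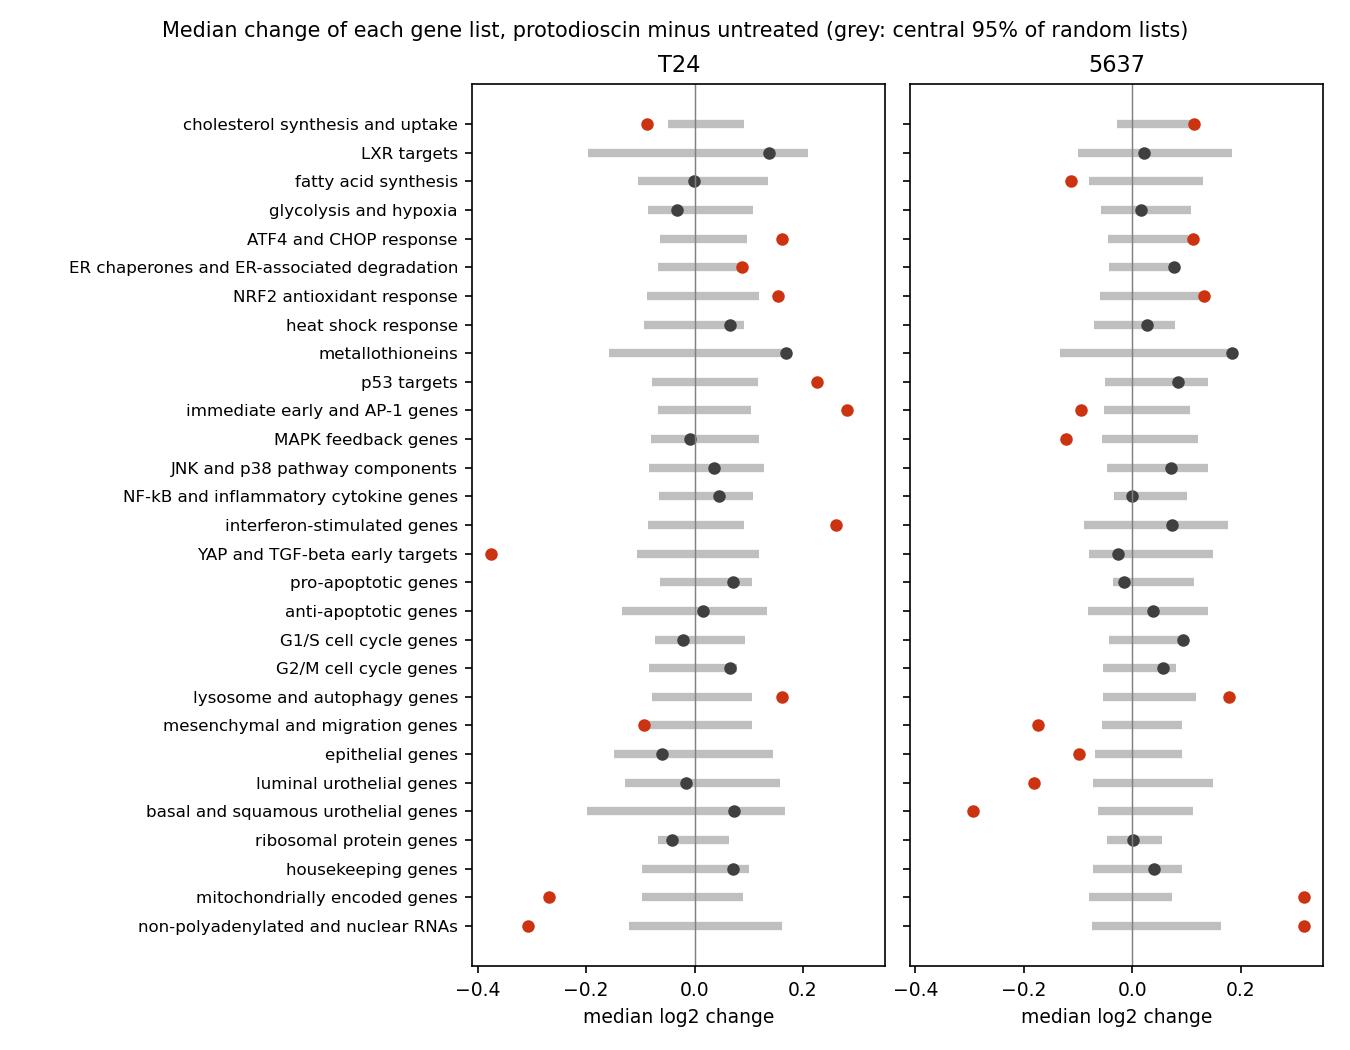
Points give the median log2 difference between treated and untreated cells for each gene list (y axis) in T24 (left) and 5637 (right), and grey bars the central 95% of 10000 random lists matched on expression; red points lie outside the bar. Lysosome and autophagy genes lie above the bar in both lines, at 0.16 and 0.18, and mitochondrially encoded genes lie on opposite sides, at -0.27 and 0.32.

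**Figure D3:**
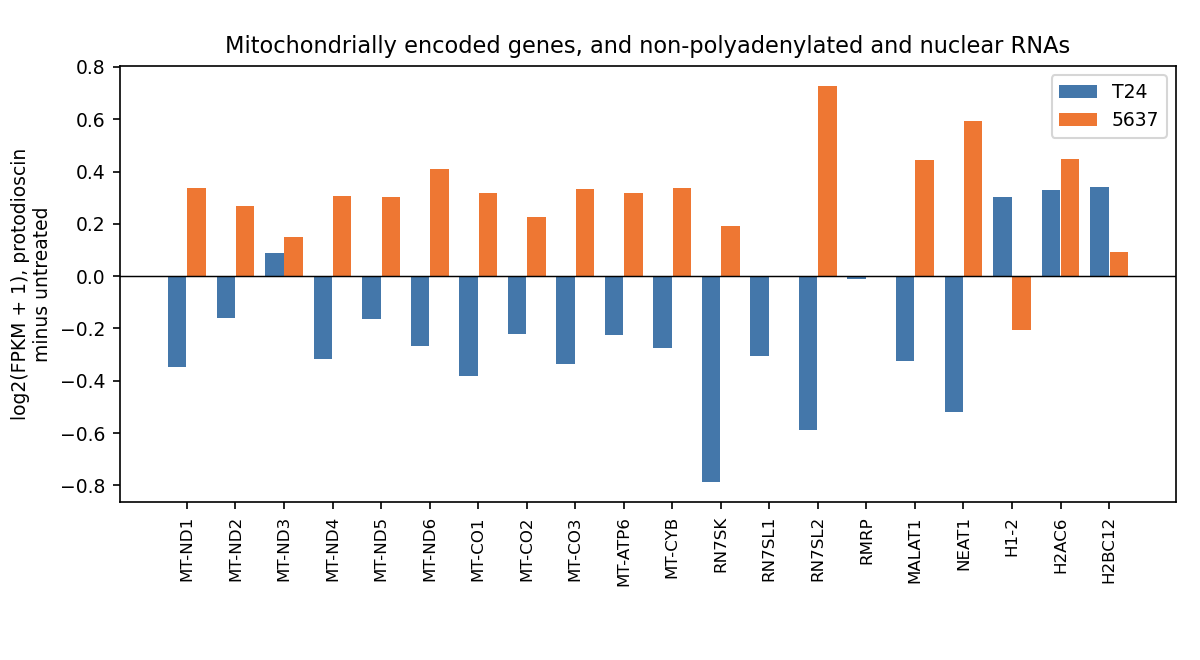
Bars give the difference of log2(FPKM + 1) between treated and untreated cells (y axis) for each mitochondrially encoded gene and each measured non-polyadenylated or nuclear RNA (x axis) in T24 (blue) and 5637 (orange), from 1 library per group. MT-CO1 lies at -0.38 in T24 and at 0.32 in 5637, MT-ND3 lies above 0 in both lines, and the histone genes H2AC6 and H2BC12 lie above 0 in both.

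The lines themselves differed widely. The line 5637 expressed basal and epithelial genes that were near or at 0 in T24, and T24 had high levels of interferon-stimulated genes. KRT6A was at 574 and 432 FPKM in untreated and treated 5637 and at 0.068 and 0 FPKM in T24 (limma coefficient 8.91, SE 0.093, adjusted p 2.2e-07). KRT5 was at 331 and 283 FPKM in 5637 and was listed at 0 in both T24 libraries, and MMP1 was at 1912 and 1530 FPKM against 3.17 and 3.55 FPKM. S100A9, a calcium-binding protein of inflamed epithelium, the chloride channel ANO1, the ligand WNT7A and the laminin chain LAMA3 were also among the largest coefficients toward 5637. In the other direction, IFI27 was at 225 and 231 FPKM in T24 and at 0.239 and 0.566 FPKM in 5637 (coefficient -7.36, adjusted p 2.6e-07). BST2, which tethers enveloped viruses, and the proteoglycan SRGN were at 203 and 228 FPKM and at 312 and 271 FPKM in T24 and were listed at 0 in 5637. The interferon genes IFI6, IFITM1 and IFIT1 and the actin-binding genes TAGLN and TPM2 completed the largest coefficients toward T24.

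Limma called 8886 of 12893 genes between the lines at an adjusted p below 0.05, 4365 higher in 5637 and 4521 higher in T24. All 12 interferon-stimulated genes were higher in T24, as were 13 of 15 G2/M genes, among them MKI67 at 116 and 132 FPKM against 44.1 and 38.4 FPKM. Higher in 5637 were 11 of 12 basal and squamous genes, 11 of 12 epithelial genes, 7 of 9 luminal genes, 11 of 15 MAPK feedback genes, 13 of 20 inflammatory cytokine genes and all 11 mitochondrially encoded genes. The adhesion gene CDH1 was at 69.6 and 72.3 FPKM in 5637 and at 0.016 and 0 FPKM in T24, and the luminal factor FOXA1 was higher in T24, at 19.9 and 19.4 FPKM against 4.84 and 4.78 FPKM. Mesenchymal genes split, with 9 of 16 higher in 5637, such as vimentin (VIM) at 304 and 267 FPKM against 68.0 and 61.4 FPKM, and 7 higher in T24, such as the repressor ZEB1 at 8.46 and 8.38 FPKM against 0.070 and 0.179 FPKM. Adjusted over the list alone, the counts were the same except 14 in place of 13 inflammatory genes, 2 in place of 3 ribosomal protein genes higher in 5637, and 0 in place of 1 non-polyadenylated and nuclear RNA higher in T24. The libraries of a line share its culture history, so line and culture were not separated.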

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

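The tests of scaling, of line or dose and of shared handling were chosen after the results were seen, and so was the restriction to genes without same-strand exon overlap. In the test of counting error, genes at 0 in a library were first taken as beyond counting error, and this was corrected to a floor of 0.5 fragments after a value had been seen. The genes and list medians selected for this part moved in opposite directions in T24 and 5637, and these differences between the lines were not tested, since each line had 1 library per group. The tests of counting error and of exon-sharing pairs cover all 2-fold differences of either line, including genes that moved alike in both, and do not single out the genes that moved in opposite directions.

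Among the genes taken by the rules for named genes, those with differences of at least 1.5-fold in opposite directions were SENP3-EIF4A1 (-2.999 in T24 and 1.79 in 5637 on the log2 scale), TOMM6 (-2.81 and 2.94), HSPE1-MOB4 (-1.48 and 0.61), NDUFC2-KCTD14 (-0.82 and 1.79), MATR3 (-1.09 and 1.66), SKP1P1 (-1.23 and 1.60), SCHIP1 (-0.97 and 1.59), KRT10 (0.69 and -1.11), SNORD14A (-1.19 and 0.75) and SNORD101 (-1.27 and 0.59). The last 3, chosen after their values were seen, share no exon on the same strand with another gene, and the others do. KRT10 overlaps KRT10-AS1 on the opposite strand, which libraries without strand do not separate. KRT10-AS1 was at 1.71 and 1.78 FPKM in T24 and at 1.84 and 1.605 FPKM in 5637. SNORD14A was at 1.83 and 0.239 FPKM in T24, and SNORD101 at 1.80 and 0.157 FPKM, and counting error is larger for such short RNAs. MATR3 here is the gene annotated as ENSG00000280987, and the other MATR3 gene was at 0.071 in T24 and -0.44 in 5637. Counting error was tested as the whole cause of the 2-fold changes, with reads estimated from FPKM. Of 106 differences of 2-fold, 13.2% (interval 7.41% to 21.2%) lay within 3 counting standard deviations of no change, and 6.60% before the correction. Taken as counts, these estimates argue against counting error as the whole cause. The differences were picked by their size, though, and the bound makes no allowance for that choice. Most of the genes share exons, however, and their FPKM comes from an estimated division of reads, so the test cannot decide for them. Genes changed in both lines count in each line, here and in the pairs below, and the intervals treat these as independent. A reassignment of reads between genes that share exons may underlie 2-fold changes at such genes: in 83.8% of 68 pairs (57 pairs, interval 72.9% to 91.6%) the gene and its partner moved apart, against 49.9% of 839 sharing pairs without a 2-fold change. A switch between transcripts in the cells would look alike in these values, so it stays open.

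Mitochondrially encoded genes had a median of -0.27 in T24 and 0.32 in 5637, and the list of non-polyadenylated and nuclear RNAs had -0.31 and 0.32. Scaling was argued against as the whole cause, since the smallest shift of the mitochondrial median in its own direction was 0.144 over both lines and 3 scalings. In a test of the yield of nuclear RNA, long noncoding genes stood against protein-coding genes at -0.104 in T24 and -0.028 in 5637. The difference was 0.076 (bootstrap interval 0.037 to 0.124), on the side set beforehand as favouring this cause. More nuclear RNA would not itself raise mitochondrial transcripts, however, so the test was afterwards taken not to decide. A response that differs between the lines or the doses cannot be told apart from a difference between single libraries, because no replicate decides whether the gap of 0.584 between the medians would recur. Within the nuclear list, MALAT1 was at 21.6 and 17.1 FPKM in T24 and at 14.9 and 20.6 FPKM in 5637, while the histone genes H2AC6 and H2BC12 were higher in both lines.

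Cholesterol synthesis and uptake genes had a median of -0.087 in T24 and 0.11 in 5637, and INSIG1, an inhibitor of sterol synthesis, was at 8.91 and 7.21 FPKM in T24 and at 5.26 and 6.80 FPKM in 5637. Immediate early and AP-1 genes had a median of 0.28 in T24 and -0.094 in 5637, although EGR1, ATF3, FOS and JUN were higher in both lines.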

How the results depend on the processing

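The restriction to genes without same-strand exon overlap was chosen after the data were seen, and the other alternatives before. Counts at 2-fold, given as higher and lower in T24, then in 5637, then in both lines, were 60, 96, 62, 59, 5 and 9 with a pseudocount of 0.1, and 6, 11, 7, 3, 1 and 0 with a pseudocount of 5, because a larger pseudocount shrinks differences. They were 12, 22, 9, 8, 1 and 1 with a filter at 5 FPKM, and 111, 135, 87, 109, 12 and 10 with TPM scaling, which raises all values against the pseudocount and the filter. For protein-coding genes they were 7, 21, 8, 11, 0 and 1, for genes without same-strand exon overlap 3, 12, 6, 8, 1 and 1, and at 1.5-fold 84, 159, 82, 91, 9 and 13. Without a filter, with median-ratio scaling and with quantile scaling all of these counts stayed within 1.5 times the main counts. The treatment effect in limma gave 2 genes with a pseudocount of 0.1 (BLOC1S5-TXNDC5 and ENSG00000267904) and 2 without exon-sharing genes (SMARCB1 and ENSG00000267904), and 0 under all other alternatives, including the fit without the block for cell line, which had 9 genes at an unadjusted p below 0.05. The difference between the lines gave 6437 to 10016 genes.

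The median of non-polyadenylated and nuclear RNAs in T24 turned from -0.31 to 0.33 with protein-coding genes alone and to 0.32 without exon-sharing genes, because 3 and 4 members, mainly histone genes, were left. The median of immediate early and AP-1 genes in 5637 turned from -0.094 to 0.015 without a filter, which adds members below 1 FPKM. Of the 25 list medians outside the central 95%, 20 to 25 kept their direction and stayed outside under each alternative, with 20 without exon-sharing genes. Those that entered the central range under at least 1 alternative were cholesterol, fatty acid, ATF4 and CHOP, NRF2, immediate early, luminal and nuclear RNA lists in 5637 and chaperone, mesenchymal and nuclear RNA lists in T24. Among the lists shared by both lines, ATF4 and CHOP targets in 5637 ranged from 0.052 to 0.12 with a lowest percentile of 94.9, and lysosome and autophagy genes ranged from 0.12 to 0.18 in T24 and from 0.12 to 0.19 in 5637. Depth limits short and low genes most, and the lack of replicates limits every value within a line.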

Other observations

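The test of shared handling and the analyses of genes without exon overlap were chosen after the results were seen. Genes of apoptosis and the cell cycle had small median differences. The median of pro-apoptotic genes was 0.071 in T24 and -0.015 in 5637, and that of anti-apoptotic genes 0.016 and 0.039. The BH3-only gene BCL2L11 was at 2.15 and 2.93 FPKM in T24 and at 6.26 and 7.05 FPKM in 5637, and BAX was at 24.8 and 26.7 FPKM and at 23.7 and 24.4 FPKM. G1/S genes had medians of -0.021 and 0.093 and G2/M genes 0.066 and 0.057, with cyclin D1 (CCND1) at 239 and 177 FPKM in T24 and at 331 and 312 FPKM in 5637. Components of the JNK and p38 pathways had medians of 0.035 and 0.071, glycolysis and hypoxia genes -0.032 and 0.016, LXR targets 0.14 and 0.022, heat shock genes 0.065 and 0.027, and metallothioneins 0.17 and 0.18. VEGFA, the angiogenic growth factor, was at 24.2 and 19.9 FPKM in T24 and at 22.1 and 17.2 FPKM in 5637. All of these medians lay within the central 95% of random lists. Metallothioneins were near its upper edge, at percentiles 96.95 in T24 and 97.46 in 5637, with all 5 and all 4 measured members above 0. G1/S genes in 5637 were at percentile 97.21.

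Inflammatory genes had medians of 0.045 and 0.00021 but split in T24, where the NF-kB inhibitor NFKBIA was at 29.5 and 45.6 FPKM (0.61) and TNFAIP3, another inhibitor of the pathway, at 21.6 and 12.5 FPKM (-0.75), with the cytokine IL1B at 22.6 and 13.5 FPKM. Ribosomal protein genes had medians of -0.042 and 0.00071 and housekeeping genes 0.071 and 0.040. Medians of the remaining pairs were 0.077 for endoplasmic reticulum chaperones, 0.084 for p53 targets, 0.073 for interferon-stimulated genes and -0.027 for YAP and TGF-beta targets in 5637, and -0.0011 for fatty acid synthesis, -0.0086 for MAPK feedback, -0.060 for epithelial, -0.015 for luminal and 0.073 for basal genes in T24. Of the markers of other cell types, COL1A1 in 5637 (6.81 and 7.52 FPKM) and CDH5 in T24 (1.57 and 0.777 FPKM) reached 1 FPKM, and no leukocyte or erythroid marker did.

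Differences with treatment were weakly correlated between the lines, with a Spearman correlation across genes of 0.153 in the lowest, 0.173 in the middle and 0.243 in the highest class of expression. A trend with transcript length, GC content or expression was argued against as the whole cause, since the correlation was 0.182 (bootstrap interval 0.164 to 0.203) after these trends were removed. Exon sharing was argued against as the whole cause as well, since the correlation was 0.202 (0.184 to 0.223) over 9358 genes without same-strand overlap and 0.210 (0.186 to 0.237) over 5603 genes without overlap on either strand. A hypothesis is that part of the correlation may be a response common to both lines, but handling shared by the treated cultures, such as a vehicle or a medium change, cannot be told apart from it, because the correlation of 0.189 would arise in both cases and the labels describe the controls as untreated.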
